A study of Mus musculus with 6 samples.

How the data were processed

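Hippocampal RNA of male mice was hybridised to 6 Affymetrix mouse arrays, 3 from Rsk2-KO mice and 3 from WT littermates, with the groups and array numbers taken from the sample titles. Per the labels, each sample was a pool of 2 hippocampi from animals aged 2 months on a C57BL/6J background, and labelled cRNA was made from 6 micrograms of total RNA. The deposited values are probe set signal intensity on a linear scale, computed with MAS5 per the submitters' processing notes; the version and settings are not given in the sources used here. MAS5 subtracts a background, summarises each probe set and scales each array to a common trimmed mean. The mean signal after trimming 2% at each end was checked and lay at 100.0 in every array, so the arrays are comparable in scale but a difference in total RNA content would be removed. Detection calls were not used here. Signals ran from 0.0142 to 7630. At most 1 probe set had an equal signal in a pair of arrays, so no array was a copy of another. The labels call the samples pools but do not say whether pools share animals, so p-values measure the spread between these pools.

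Of 22690 probe sets, 20393 had 1 gene symbol in the GEO platform annotation, 691 had several and 1606 had none; 20351 of the first were found by Entrez ID in the RefSeq table of GRCm38.p6, which was used only for current symbols and gene spans. Probe sets with several genes or none were not named, and control probe sets were left out. Log2 signals were used as deposited, without further normalization. Probe sets below the 40th percentile of mean log2 signal, a signal of 19.2, were left out, which kept 13579 probe sets; each gene was represented by its brightest probe set, giving 7867 genes. Signals near background are noisy in MAS5, and the filter limits this but does not remove it.

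The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, group as the only term, Benjamini-Hochberg adjustment). Probe set names and gene spans were matched in Python 3.11.15. Values for single probe sets come from the same model over all kept probe sets. With 3 arrays against 3, an exact permutation test cannot give a two-sided p below 0.1, so none is given. The median standard error of a log2 difference was 0.189. On simulated data with 201 of 7867 genes changed, 20 simulations recovered 23.7% of 1.5-fold, 77.2% of 2-fold and 95.8% of 3-fold changes. A mean of 9.4 false calls was made. A list shifted by 0.2 was recovered in 100% of simulations, with 0.2 other lists called on average. The simulated noise was independent between genes and held no structure between arrays. The shifted list was oxidative phosphorylation, whose estimated correlation on the real arrays was 0.266. These rates therefore may not hold for the real arrays.

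In advance, 41 gene lists were fixed for receptors, synaptic, signalling, metabolic and stress functions and for markers of cell types and neighbouring regions; 38 had at least 3 measured members. NMDA receptor, metabotropic glutamate receptor and blood cell lists had fewer and were not tested. Lists were tested with camera (preset correlation 0.01, intensity trend), with an estimated correlation and with fry (its directional test) as alternatives; fry's mixed test, for differences in either direction, is given apart. The genes named were also set by rule beforehand: Rps6ka3; the AMPA subunits Gria1 to Gria4, Sp1, Rps6ka1, Rps6ka2 and Rps6ka6; in each direction up to 15 genes with the smallest p among those past the threshold without overlap or, as fewer than 10 passed, the 10 with the smallest p and no overlap; in each direction the 5 with the largest difference among those with an unadjusted p of 0.01 and no overlap; and up to 4 members with the smallest p of each list. Where another kept probe set had the opposite sign this is stated for all these genes except most of those named as list members. A gene that the annotation used does not name, such as Rps6ka1, was not analysed here.

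Alternatives set before the data were examined were quantile normalization, median centring, offsets of 16 and 64, no filter or a filter at the 60th percentile, no intensity trend, a robust prior, array weights, a block for the array number, the mean of all probe sets per gene, exclusion of probe sets ending in _x_at or _s_at, each array left out in turn, and an adjusted p of 0.1. Chosen after seeing the data were a batch block for the arrays numbered 3, exclusion of both these arrays, removal of each array's lowess trend of deviation on gene span, a block for arrays split by their highest signal, and a test of the interaction with the arrays numbered 3. The labels give no hybridisation dates, so batches were looked for only in the signals.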

Results

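Gene expression was measured in the hippocampus of 2-month-old male mice on 6 arrays, 3 labelled Rsk2-KO and 3 labelled WT. Rsk2 is the protein kinase encoded by the X-linked gene Rps6ka3, which acts downstream of ERK; loss of its human counterpart underlies Coffin-Lowry syndrome, a form of intellectual disability. Each array held RNA from a pool of 2 hippocampi. The question was which molecular pathways differ in expression between knockout mice and their normal littermates. All 6 arrays gave a signal for 22690 probe sets, and the trimmed mean signal lay between 100.034 and 100.037 in every array. After dim probe sets were left out, 7867 genes were compared.

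Rps6ka3 itself was not lower on the arrays labelled Rsk2-KO. Its brightest probe set, 1455206_at, gave signals of 99.2, 98.4 and 87.0 on these arrays and 74.2, 59.7 and 89.2 on the arrays labelled WT. The means were 94.8 ± 6.81 and 74.4 ± 14.8 (SD, n = 3 each), a log2 difference of 0.37 (SE 0.18) that did not pass the test (adjusted p = 0.617). Without WT 2 the log2 difference was 0.22; it was 0.57 within the arrays numbered 1 and 2 and −0.04 between the arrays numbered 3. A dimmer probe set, 1427299_at, gave a log2 difference of 0.54 (SE 0.37). The place of these probe sets relative to the disrupted part of the gene was not analysed here, so they do not check the labels, and groups are named below by the label of the array. Rps6ka1, Rps6ka2 and Rps6ka6, which encode the related kinases, were not analysed here.

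The AMPA receptor subunits, which form the main fast excitatory receptors of hippocampal synapses, were examined next because they have been linked to this knockout. Gria2, whose subunit limits calcium entry through the receptor, had a mean signal of 1659 ± 56.8 on the arrays labelled Rsk2-KO and 1393 ± 241 on those labelled WT (SD, n = 3 each) at its brightest probe set. The log2 difference was 0.27 (SE 0.15, adjusted p = 0.621), and 0.14 without WT 2. A second Gria2 probe set, 1453098_at, differed more: 363 ± 65.3 against 180 ± 62.2, a log2 difference of 1.05 (SE 0.24), with no overlap between the groups but an adjusted p of 0.661 among all probe sets. Its signals were 423 and 371 against 132 and 158 on the arrays numbered 1 and 2, but closer, 294 against 250, on those numbered 3. The log2 difference of Gria2 at the brightest probe set was 0.40 within the arrays numbered 1 and 2 and 0.0050 between the arrays numbered 3. Gria3 and Gria4 had log2 differences of 0.43 (SE 0.19) and 0.53 (SE 0.27), both with an adjusted p of 0.617, and Gria4, unlike Gria3, was higher on every array labelled Rsk2-KO (0.35 without Rsk2-KO 3). The mean WT signal of Gria4, 19.6 ± 2.14, lay near the filter of 19.2. Gria3 was 0.71 within the arrays numbered 1 and 2 and −0.12 between the arrays numbered 3. Gria1 differed by −0.09 (SE 0.16) at its brightest probe set and by 0.44 at another, of the opposite sign; at the brightest it was 0.00044 without Rsk2-KO 2 and 0.0025 without WT 3. Sp1, a transcription factor known to act on the Gria2 promoter, differed by 0.39 (SE 0.39, adjusted p = 0.748), and by 0.025 without WT 2, 0.20 without Rsk2-KO 3, 0.70 without Rsk2-KO 2 and 0.80 without WT 3.

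**Figure D1:**
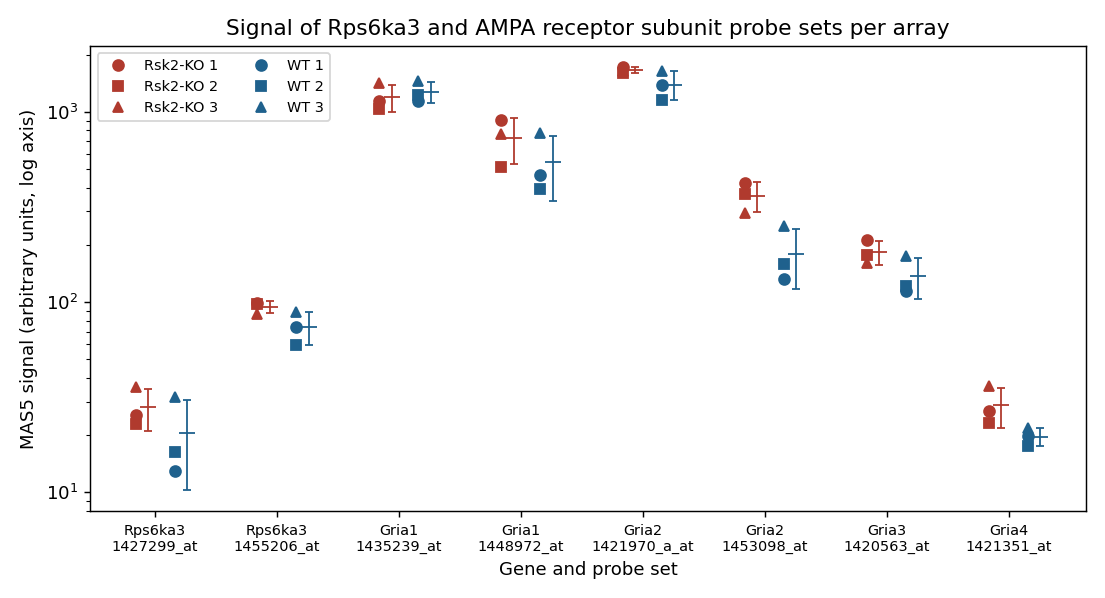
MAS5 signal (log axis) of each kept probe set of Rps6ka3 and the AMPA receptor subunits on the 6 arrays; symbols give the array number, colours the label, and the crossed bars the mean and SD of 3 arrays. The Rsk2-KO points of Gria2 probe set 1453098_at, from 293.5 to 423.2, lie above the WT points, from 132.0 to 250.3. The nearest points, 293.5 and 250.3, are the arrays numbered 3.

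As a list, the 7 measured AMPA, kainate and delta receptor genes did not shift against the other genes (median log2 difference 0.18, 4 higher and 3 lower, camera adjusted p = 0.893). The kainate receptor genes Grik2 and Grik5 were lower on every array labelled Rsk2-KO, by log2 differences of −0.42 and −0.25. In the mixed test of fry, which asks whether members differ in either direction, this list had an adjusted p of 0.0429, and so did the 25 reported RSK substrates, but no other list came under 0.05. In the directional test of fry, which asks for a shift one way, the adjusted p was 0.883 for this list and 0.559 for the RSK substrates. Neither compares a list with other genes. The AMPA list was chosen with knowledge of earlier work on this knockout and is not independent evidence. Among the RSK substrates, Pdcd4 (0.37) and Tbk1 (0.39) were higher and Eif4b (−0.45) and Ranbp3 (−0.37) lower. No member of either list passed over all genes or adjusted over the list alone.

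Across all genes, 0 were called higher and 0 lower in limma at an adjusted p of 0.05, and the lowest adjusted p was 0.617. With array weights, 42 passed higher and 9 lower. At an unadjusted p of 0.05 that fit gave 2042 genes, near the 2023 of the fit without both arrays numbered 3. Past the adjusted threshold the 2 fits differed, as the fit without these arrays called 233 higher and 51 lower. In the main fit there were 589 genes at an unadjusted p of 0.05, where 393 are expected by chance. At 0.01 there were 85, where 79 are expected. The groups did not overlap in 1119 genes, or 14.2%, against 10% by chance; 430 of these were higher and 689 lower on the arrays labelled Rsk2-KO. Both criteria, an unadjusted p of 0.01 and no overlap, were met by 56 genes higher and 28 lower. The counts of these moved by over 1.5 times with 1 array left out: 8 higher and 11 lower without Rsk2-KO 1, 12 and 15 without Rsk2-KO 2, 170 and 78 without Rsk2-KO 3, 16 and 10 without WT 1, 325 and 78 without WT 3; without WT 2 the higher count was 30.

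None of the genes named next passed the adjusted test on all 6 arrays without array weights or a block, and their values are given as measured. Among the genes with the smallest p and no overlap, those higher on the arrays labelled Rsk2-KO were Gnb1, Ssb, Stxbp3, Nr1d2, Rb1, Lrrtm2, Ptpn2, Hspa4, Ap5m1 and Arhgap12, from 1.54-fold to 2.16-fold. With array weights, 9 of these 10, all but Ap5m1, passed (adjusted p from 0.0318 to 0.0499). All but Ap5m1 differed less between the arrays numbered 3 than within the arrays numbered 1 and 2. Hspa4 differed by 0.09 against 1.27, Lrrtm2 by 0.32 against 1.51 and Ap5m1 by 0.91 against 0.77. Gnb1, a G protein beta subunit, had signals of 461 ± 29.4 against 271 ± 31.7 (SD, n = 3 each), a log2 difference of 0.77 (SE 0.14), but its other probe set did not differ (136 ± 16.6 against 131 ± 5.35, log2 difference 0.04, SE 0.15). Lrrtm2, a synaptic adhesion protein that organises excitatory synapses, had 70.1 ± 19.0 against 32.3 ± 8.54, a log2 difference of 1.11 (SE 0.26). Ptpn2, a tyrosine phosphatase, differed by 1.03 (SE 0.24), and Hspa4, a heat shock protein of the Hsp110 family, by 0.88 (SE 0.23). Other probe sets differed less, by 0.24 and 0.45 for Ptpn2, 0.35 and 0.63 for Hspa4, 0.23 to 0.76 for Ssb, 0.50 for Ap5m1 and 0.05 for Nr1d2. Of the genes with the largest differences, Marveld1 (1.13), Abhd18 (1.02) and Max (1.01), the dimerisation partner of Myc, were also higher. Another probe set of Marveld1 had the opposite sign, −0.37, and with an offset of 64 the difference of Marveld1 was 0.34. The mean WT signals of Marveld1 (20.9 ± 9.43) and Abhd18 (14.7 ± 3.71) lay near or below the filter of 19.2.

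The lower genes were Vtn, Erdr1, Unc119, Rasl10a, Mvk, Gstm1, Cnn2, Strn4, Nkain4 and Tst, from 1.49-fold to 3.00-fold. With array weights, 7 of these 10, all but Cnn2, Nkain4 and Tst, passed (adjusted p from 0.0318 to 0.0499). Between the arrays numbered 3 the 10 differed by −0.23 for Gstm1 to −1.45 for Erdr1, against −0.88 and −1.65 within the arrays numbered 1 and 2. Erdr1 had the largest difference, with signals of 117, 246 and 316 on the arrays labelled Rsk2-KO and 513, 552 and 866 on those labelled WT, a log2 difference of −1.59 (SE 0.33). With the arrays numbered 3 as a batch block, Erdr1 was the 1 gene past the threshold (adjusted p = 0.0408). The only kept probe set of Erdr1 ended in _x_at, so the alternative without _x_at and _s_at probe sets could not check this gene. Vtn, the adhesion protein vitronectin, had 185 ± 24.6 against 309 ± 20.2, a log2 difference of −0.75 (SE 0.15). Mvk, mevalonate kinase of the cholesterol pathway, differed by −0.86 (SE 0.23) and had another probe set of the opposite sign, 0.43. Gstm1, a glutathione transferase, differed by −0.66 (SE 0.18), and 1 of its other probe sets had the opposite sign, 0.25. Trem2, a microglial receptor, and Shc1, an adaptor that links receptors to Ras, differed by −1.07 (SE 0.32) and −0.87 (SE 0.25). The mean Rsk2-KO signals of Trem2 (17.0 ± 6.45), Shc1 (20.1 ± 2.67) and Cnn2 (16.6 ± 3.06) lay near or below the filter of 19.2.

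The main axis of variation did not follow the labels. The arrays numbered 3, 1 of each label, stood apart on the first principal component, which held 40.2% of the variance, with scores of 20.03 and 23.6 against −6.36 to −15.6 for the other arrays. The second component, with 27.8% of the variance, put the arrays labelled Rsk2-KO (17.4, 13.7 and 1.32) above those labelled WT (−19.4, −12.4 and −0.55), with the arrays numbered 3 closest together. Of the 3′ to 5′ signal ratios, a sign of RNA quality, those of Actb were highest in the arrays numbered 3 (2.24 and 2.22, against at most 1.63 elsewhere), those of Tfrc lowest (2.09 and 1.86, against 2.69 to 3.51), and those of Gapdh did not set them apart. The 5′ probe set of Tfrc was below the signal filter. For pyruvate carboxylase, 5′ signals were lowest in the arrays numbered 3 (17.3 and 22.0, against 24.2 to 38.3), near the filter. Its 3′ signals were 77.3 and 82.1, against 56.1 to 81.3, so its ratio was highest there. Without this pair, with 2 arrays in each group, 233 genes passed higher and 51 lower, Gnb1, Lrrtm2, Hspa4, Vtn and Erdr1 among them. Between the arrays numbered 3, 134 of these 284 genes, or 47.2%, had the same sign, against 51.8% of all genes, and the median log2 difference of the 284 in the called direction was −0.01. A test of whether the difference itself changed between the pair numbered 3 and the other arrays called 0 genes (lowest adjusted p = 0.181); it has 1 array per label on one side, which is assumed to vary like the others.

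Of 38 gene lists tested with camera, 4 passed an adjusted p of 0.05, 3 lower and 1 higher on the arrays labelled Rsk2-KO. For each of these 4, the adjusted p = 0.925 with an estimated correlation, so no call was left. Oxidative phosphorylation genes were lower, with 61 of 70 measured members below 0 and a median log2 difference of −0.12 (adjusted p = 0.00938). Examples were Uqcrc1 of complex III (−0.46, SE 0.17) and Cox8a of complex IV (−0.39, SE 0.16). Cytosolic ribosomal protein genes were lower in 37 of 43 members, with a median of −0.14 (adjusted p = 0.0278); Rpl6 and Rpl37a differed by −0.30 and −0.35. Cholesterol biosynthesis genes were lower in 16 of 19 members, with a median of −0.24 (adjusted p = 0.0319); besides Mvk, Fdps, Ebp and Sqle differed by −0.33, −0.41 and −0.33. Voltage-gated ion channel genes were higher in 22 of 33 members, with a median of 0.16 (adjusted p = 0.0319). The potassium channels Kcnn2 and Kcnj3 differed by 0.41 and 0.42 (0.25 and 0.20 between the arrays numbered 3). The sodium channels Scn1a and Scn2a differed by 0.60 and 0.65, but by −0.18 and −0.02 between the arrays numbered 3. No member of these 4 lists passed over all genes, and 0 passed adjusted over the list alone. After quantile normalization 0 of the 4 lists passed, with medians of −0.07 for oxidative phosphorylation, −0.09 for ribosomal proteins, −0.26 for cholesterol biosynthesis and 0.14 for ion channels. None of the 4 passed when Rsk2-KO 1, Rsk2-KO 2 or WT 1 was left out, and the calls were also lost for ribosomal proteins and ion channels without WT 2 and for cholesterol biosynthesis without WT 3. The median of cholesterol biosynthesis moved to −0.11 without Rsk2-KO 1, −0.15 without Rsk2-KO 2 and −0.16 without WT 3, and that of ion channels to 0.09 without Rsk2-KO 1, 0.09 without WT 1 and 0.10 without WT 2.

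These list differences were larger within the arrays numbered 1 and 2, where the medians were −0.22 for oxidative phosphorylation, −0.20 for ribosomal proteins, −0.28 for cholesterol biosynthesis and 0.28 for ion channels. Between the arrays numbered 3 they were 0.04, 0.02, −0.03 and −0.10. Gene size moved with these differences, to an extent that varied between lists. Across genes, the log2 difference correlated with genomic span (Spearman 0.236 over 7861 genes, which are not independent replicates). Oxidative phosphorylation and ribosomal protein genes are short, with median spans of 7.39 kb and 3.35 kb, and ion channel genes long, at 186 kb. All genes in the bin with a median span of 3.02 kb had a median log2 difference of −0.12, against −0.14 for ribosomal proteins. In the bins of 6.25 kb and 10.1 kb it was −0.12 and −0.07, against −0.12 for oxidative phosphorylation. The bin of 197 kb had 0.07, against 0.16 for ion channels. Over all genes tested the median was −0.04. Cholesterol biosynthesis genes had a median span of 16.1 kb, and all genes in the bins with median spans of 14.7 kb and 20.2 kb had median log2 differences of −0.09 and −0.05, smaller in size than the −0.24 of that list. The arrays WT 1 and WT 2 had correlations of −0.207 and −0.213 between a gene's deviation and its span, the other 4 arrays from 0.0813 to 0.211. WT 1 and WT 2 also had the lowest signals of the 5′ probe set for 18S ribosomal RNA, 562 and 327, against 858 to 1580 on the other arrays. With each array's trend on span removed, an alternative chosen after seeing the data, no list passed. The median of oxidative phosphorylation became −0.06 (adjusted p = 0.444) and that of ribosomal proteins −0.03 (adjusted p = 0.885). More of the median was left for cholesterol biosynthesis, at −0.17 (adjusted p = 0.140), and ion channels, at 0.14 (adjusted p = 0.444).

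**Figure D2:**
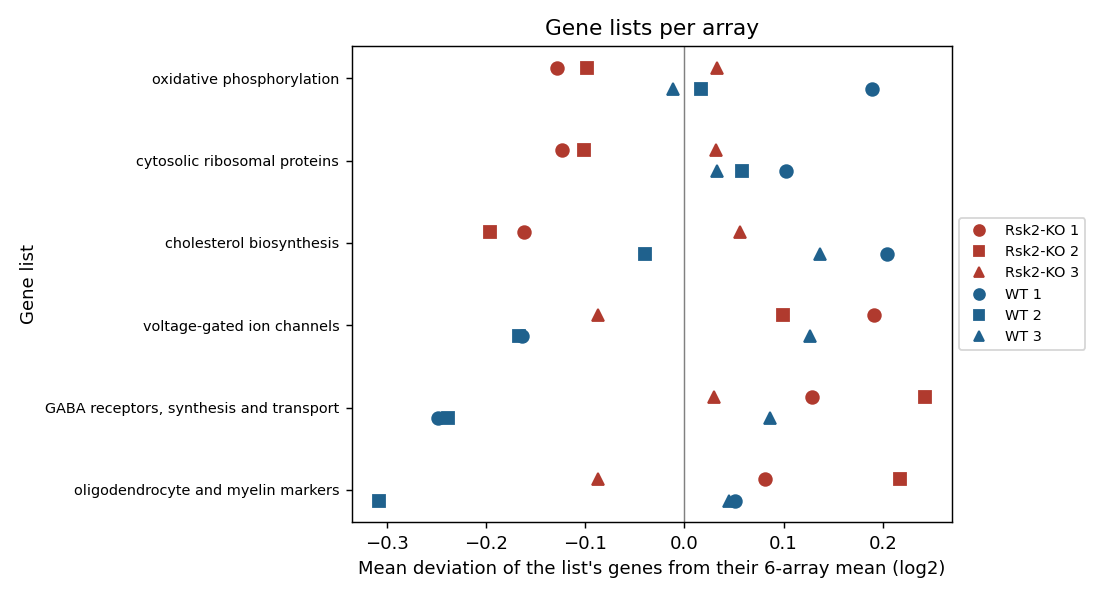
Mean deviation (log2) of the genes of 6 lists from their 6-array mean, 1 symbol per array; symbols give the array number and colours the label. For oxidative phosphorylation, Rsk2-KO 1 and Rsk2-KO 2 lie at −0.13 and −0.10, WT 1 at 0.19, WT 2 at 0.02, and the arrays numbered 3 at 0.03 and −0.01.

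**Figure D3:**
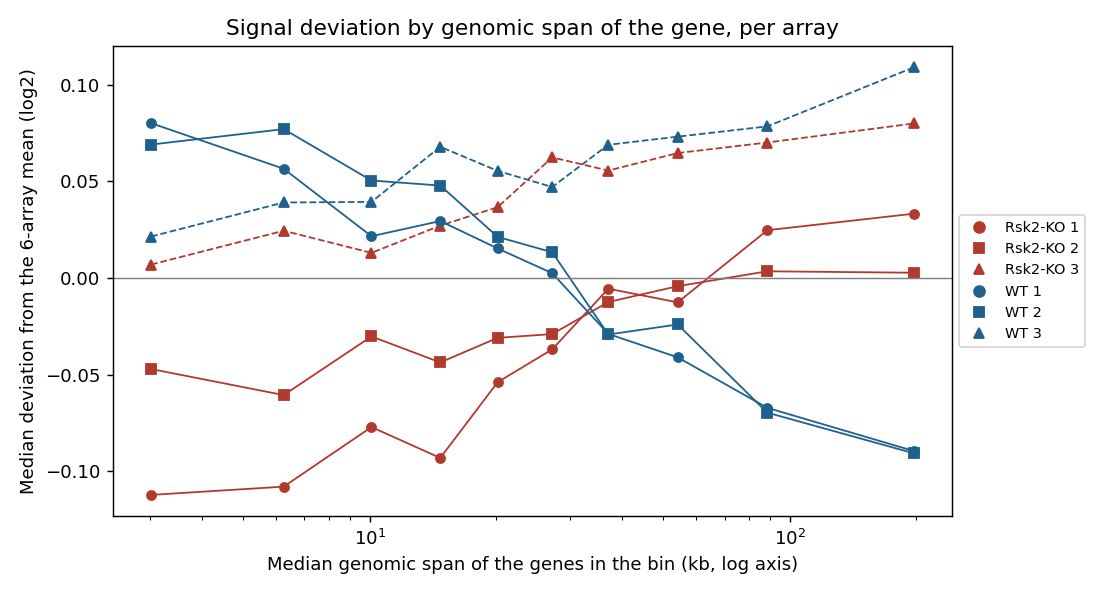
Median deviation (log2) of genes from their 6-array mean in bins of genomic span (kb, log axis), 1 line per array; dashed lines are the arrays numbered 3. In the bin of shortest genes, Rsk2-KO 1 lies at −0.11 and WT 1 at 0.08.

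Synaptic and signalling lists did not pass. Postsynaptic scaffold genes had 11 members higher and 11 lower (adjusted p = 0.269). The AMPA receptor auxiliary subunits Cacng8 (0.87, SE 0.24) and Cacng2 (0.60, SE 0.20) and the scaffold Dlg4 (0.40, SE 0.14) were higher on every array labelled Rsk2-KO, and Cacng3 (−0.34, SE 0.15) was lower on every one. GABA receptor, synthesis and transport genes were higher in 8 of 10 members, with a median of 0.29 (adjusted p = 0.146), and passed only without both arrays numbered 3 (adjusted p = 0.0333). Gabbr1 (−0.26) and Gabrd (−0.30) were lower, but the 2 other kept probe sets of Gabbr1 had the opposite sign. Gabrd was 0.10 between the arrays numbered 3. Gabra2 differed by 1.78 within the arrays numbered 1 and 2 and by −0.75 between those numbered 3. Immediate-early genes (median −0.05, adjusted p = 0.893), the ERK pathway (median −0.05, adjusted p = 0.906), the mTOR pathway (median −0.03, adjusted p = 0.893) and presynaptic genes (median −0.10, adjusted p = 0.893) did not differ from other genes; a p above the threshold does not show that they were equal.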

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

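The test of RNA degradation in the arrays numbered 3, the reading of the quantile-normalized lists by their medians, and the comparisons without these arrays or with the span trend removed, were chosen after the result was seen.

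Control probe sets were outside the gene comparison, and 4 of the 35 above the filter were higher on every array labelled Rsk2-KO while 0 were lower; chance gives about 10% without overlap in either direction. The folds were 1.40 and 1.32 for the bioB 3′ and 5′ probe sets and 1.25 for the bioD 3′ probe set, all for bacterial transcripts added as hybridisation controls, and 1.49 for the 3′ probe set of the mouse transferrin receptor. Other probe sets of bioB and bioD overlapped between the labels, with folds from 0.995 to 1.40 for bioB and from 1.19 to 1.34 for bioD.

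A gradient on gene span, technical or not, may account for part of the 4 gene lists past the threshold. Removing it would also remove a difference by genotype that varied with span, so the cause of the gradient stays open for every list. With each array's trend on gene span removed, the camera adjusted p was 0.885 for ribosomal proteins. Their median went from −0.14 to −0.03 (SD of members 0.126 before and 0.127 after), which is what a span trend predicts. For oxidative phosphorylation (0.444; median −0.12 to −0.06, SD 0.131 and 0.126), ion channels (0.444; 0.16 to 0.14, SD 0.322 and 0.318) and cholesterol biosynthesis (0.140; −0.24 to −0.17, SD 0.251 and 0.256) the call ended but at least 0.5 times the median was left, so the trend and a difference by genotype cannot be told apart. After quantile normalization 0 of the 4 lists passed, but the medians were −0.07, −0.09, −0.26 and 0.14 for oxidative phosphorylation, ribosomal proteins, cholesterol biosynthesis and ion channels (SD of members 0.132, 0.120, 0.256 and 0.324), so the lost calls do not decide whether scaling plays a part. Of the 10 splits of the arrays into 3 and 3, 4, that by label included, gave as many lists (real 4, highest other 5); the splits are too few for a share under 0.05, and genotype stays open.

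Some other groupings of the arrays gave more genes than the labels did. For the 0 genes past the threshold the comparison decides nothing, since all 10 splits, that by label included, give at least 0 (highest other 102). For genes without overlap at an unadjusted p of 0.01, 3 splits gave at least the real 84: that by label and 2 others, with 231 and 445, while the remaining 7 gave 2 to 75. These 10 splits are too few for a share under 0.05. The highest counts of the 2 kinds, 102 and 445, both came from Rsk2-KO 1, Rsk2-KO 2 and WT 2 against the rest. This is also the split by highest signal in the array (4561 to 4832 against 7080 to 7630). On every array but WT 1 that signal was of a control probe set, outside the gene comparison. Whether the match reflects a structure of the samples cannot be told from the counts alone. With that split as a block the counts were close to those without it, 57 higher and 33 lower against 56 and 28, and 0 genes passed the adjusted test in both. The lists did change under this block: ion channels (median 0.16, adjusted p = 0.196) and cholesterol biosynthesis (median −0.12, adjusted p = 0.273) no longer passed, while oxidative phosphorylation (0.0433) and ribosomal proteins (0.0416) did.

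The arrays numbered 3 stood apart from the others, and the calls made without them are not explained by a shift common to both: such a shift cancels between the pair, yet 47.2% of the called genes had the same sign there, against 51.8% of all genes; the median log2 difference of the called genes in the called direction was −0.01. RNA degradation was tested on the 3′ to 5′ ratios of 3 control transcripts, and 1 of them was higher in both arrays numbered 3 than in every other array. This was Actb (2.24 and 2.22 against at most 1.63 elsewhere), while Tfrc had its lowest ratios there (2.09 and 1.86 against 2.69 to 3.51). Only the 3′ probe set of Tfrc was above the signal filter, so its ratio rests on a dim 5′ signal and cannot decide. A further control, pyruvate carboxylase, was not part of the test. Its 5′ signals, near the filter, were lowest in the arrays numbered 3 (17.3 and 22.0 against 24.2 to 38.3). Its 3′ signals were 77.3 and 82.1 there against 56.1 to 81.3, so its ratio was highest there. Degradation in these 2 arrays stays open. Whether the difference between labels itself changed in this pair was tested as an interaction, which called 0 genes (lowest adjusted p = 0.181) with 2 residual degrees of freedom, so a batch acting on the labels differently and a difference between the pools stay open.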

How the results depend on the processing

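The comparisons without the arrays numbered 3, with them as a batch block, with the highest-signal block and with the span trend removed were chosen after seeing the data. Rps6ka3 and Gria2 kept their sign and stayed above the threshold in every alternative run, from 0.20 to 0.57 and from 0.14 to 0.66. The 0 genes higher and 0 lower became 42 and 9 with array weights, 233 and 51 without both arrays numbered 3 and 0 and 1 with these arrays as a batch block; apart from the replicate block, given next, every other alternative, each array left out included, called 0. For the arrays numbered 2 and 3, deviations from the group mean correlated at 0.37 and 0.40 between labels, the highest value for each of these arrays. For those numbered 1 the correlation was 0.07, and Rsk2-KO 1 correlated best with WT 2 (0.20). Whether the array numbers pair the samples thus cannot be told. The replicate block called 0 higher and 1 lower, Erdr1 (adjusted p = 0.000204), whose only kept probe set ended in _x_at. The replicate block gave 117 and 74 genes without overlap at an unadjusted p of 0.01. The 56 higher and 28 lower genes of that kind were 193 and 169 with array weights, 123 and 88 with the batch block, 566 and 255 without both arrays numbered 3, and 47 lower with no filter; leaving out 1 array gave 8 to 325 and 10 to 78. The 1 list higher became 0 with quantile normalization, without _x_at and _s_at probe sets, with an estimated correlation, directional fry, the highest-signal block or the span trend removed, and 3 without both arrays numbered 3; the 3 lists lower became 0 with quantile normalization, an estimated correlation, directional fry or the span trend removed. The cholesterol biosynthesis call was also lost with the 60th percentile filter (adjusted p = 0.297), the mean of probe sets (0.105), without _x_at and _s_at probe sets (0.0634), without WT 3 (0.128) and with the highest-signal block (0.273). Its highest adjusted p, with the estimated correlation, was 0.925. Without WT 2 the ion channel (0.195) and ribosomal protein (0.0509) calls were lost. Leaving out 1 array gave 0 to 1 and 0 to 3 lists, with 0 in both directions without Rsk2-KO 1, Rsk2-KO 2 or WT 1. Of 3643 log2 differences of 168 named genes under alternatives, 3561 kept sign and side, 56 passed only in the alternative and 26, in 16 genes, changed sign. Without _x_at and _s_at probe sets, Marveld1 was −0.37, Dbp −0.028 and Psmd11 0.12, as another probe set stands for the gene; with the mean of probe sets Gria1 was 0.17. Array weights gave Pdgfra −0.034 and Rarres2 −0.068. Without both arrays numbered 3, Pdgfra was −0.019, Rarres2 −0.33 and Igf2 0.026. The highest-signal block gave Olig1 0.010 and Pou3f1 −0.00333, and the span trend removed Olig1 0.022. With 1 array left out, the sign changed within −0.22 to 0.00254 for Gria1 (positive without Rsk2-KO 2, at 0.000439, or WT 3), −0.00882 to 0.51 for Vcan (negative without WT 1), −0.24 to 0.061 for Olig1 (positive without WT 1), −0.020 to 0.16 for Pdgfra (negative without Rsk2-KO 3), −0.15 to 0.48 for Rarres2 (negative without WT 3), −0.00938 to 0.33 for Tdo2 (negative without WT 1), −0.14 to 0.41 for Penk (negative without Rsk2-KO 2), −0.089 to 0.29 for Rgs9 (negative without WT 2), −0.075 to 1.21 for Slc17a6 (negative without Rsk2-KO 2), −1.09 to 0.39 for Tbr1 (positive without Rsk2-KO 3, or WT 2 at 0.059) and −0.17 to 0.53 for Kdm5d (negative without WT 1, or Rsk2-KO 1 at −0.000877). Where not stated, the cause was not tested. The number of arrays limits the precision.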

Other observations

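The comparisons within and without the arrays numbered 3 were chosen after the data were seen.

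Markers of other cell types in the dissected hippocampus gave no list past the threshold; the lowest adjusted p of the 15 marker lists was 0.291, for oligodendrocyte and myelin markers (median 0.12, 10 of 16 members higher), which passed only without both arrays numbered 3 (adjusted p = 0.0366). Mobp and Ugt8a, both of myelin, had log2 differences of 0.77 and 1.04 within the arrays numbered 1 and 2 and −0.22 and −0.11 between those numbered 3. Microglial markers had a median of −0.12 (12 of 18 lower, adjusted p = 0.691), with Trem2 and Tyrobp at −1.07 and −0.32 but Cx3cr1 at 0.65 (1.10 within the arrays numbered 1 and 2, −0.25 between those numbered 3). Endothelial and mural markers were split, 9 higher and 9 lower (adjusted p = 0.893), with Vtn at −0.75 and Rgs5 at 0.48; Vtn passed adjusted over the list alone. Astrocyte (median −0.09), interneuron (0.07), oligodendrocyte precursor (−0.06), choroid plexus (0.10), dentate granule cell (0.02), immature neuron (−0.08), striatal (0.10), thalamic (0.08) and neocortical markers (0.06) each had an adjusted p of 0.893. CA1 markers had a median of 0.04 (adjusted p = 0.358), with Man1a at 0.60 passing adjusted over the list alone. CA3 and CA2 markers had −0.07 (adjusted p = 0.906) and meningeal markers 0.0016 (adjusted p = 0.987), both with a median of the opposite sign to the test.

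Heat shock and ER stress genes had 14 members higher and 12 lower (adjusted p = 0.358). On every array labelled Rsk2-KO, 4 members were higher, among them the chaperones Pdia4 (0.75), Hsp90aa1 (0.50) and Pdia3 (0.41), and 2 members were lower. In the circadian clock list (median 0.04, adjusted p = 0.827), the repressor gene Nr1d2 was higher by 0.63 and passed adjusted over the list alone, and Dbp differed by 0.50, while Arntl, which encodes the activator BMAL1, differed by −0.58 and Cry1 by −0.73. Proteasome genes had a median of −0.07 (adjusted p = 0.439). Medians of 0.08 for interferon response, −0.04 for apoptosis, −0.0034 for glucocorticoid-responsive genes, −0.01 for actin regulation, −0.06 for monoamine receptors and −0.16 for RNA editing and Gria2 promoter regulators came with adjusted p of 0.987, 0.987, 0.906, 0.893, 0.893 and 0.893. The X-chromosome neighbours of Rps6ka3 had a median of 0.02 (adjusted p = 0.270), with Txlng at 0.58. The Y-linked genes Eif2s3y and Uty differed by 0.56 and 0.30, and the list had an adjusted p of 0.267.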
